A study of Homo sapiens with 4 samples.

How the data were processed

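The series holds 4 Agilent SurePrint G3 Human Gene Expression arrays of normal human lung fibroblasts, purchased primary cells grown with serum per the labels, sampled at 0 h and after 1, 4 and 24 h with 10 ng/ml IL-13. Each time point is 1 array, so no time point has a replicate. Per the labels' protocols, total RNA was labelled with Cy3 by a low-input amplification kit. Per the file headers, the 4 arrays were on 1 slide, were scanned on 1 day in 1 channel and were read with the same extraction protocol, so slide and scan day could not separate them. Extraction used Agilent Feature Extraction 11.5.1.1, per the submitters' processing notes. The deposited scanner files give the intensity of each spot as a processed signal, background-subtracted and detrended within the array by that software per the file headers, together with the median spot and local background intensity. They were not normalized between arrays. The deposited value table of the series holds the same processed signal multiplied by 1 constant per array, 4.77, 4.77, 4.64 and 4.94 for 0, 1, 4 and 24 h (the ratio varied by about 1e-09 between spots). Its values are linear and not centred, with column medians of 75.7, 76.5, 70.1 and 67.9. How the constants were chosen is not given in the sources used here.

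For the main values, log2 of the processed signal was taken and the 75th percentile of the array's non-control spots subtracted. That percentile was 254.9, 256.6, 252.3 and 230.8 intensity units at 0, 1, 4 and 24 h. Control spots were left out, as were spots flagged non-uniform or as population outliers (75, 95, 95 and 84 per array). The number of saturated spots was 0. Repeated spots of a probe were averaged, and a probe counted as well above background where at least 50% of its spots carried that mark. The files name probes by accession. Of 58201 probes, 33080 carried a RefSeq accession, and 31104 of these matched a gene in the RefSeq table for GRCh38.p14, compared without versions. The array files refer to an older build, so the table was used for gene names and for which genes neighbour each other, and no coordinates are given. Of 22439 matched genes, 111 were left out by the rule below, 1 had its probe flagged on an array, and 22327 were analysed. A gene was represented by its probe well above background on the most arrays, with ties going to the brightest. Of the analysed genes, 16035 were well above background on at least 1 array and 14654 on all 4. More than 1 probe was present for 6754 genes. Among called genes that had another measurable probe, the other probes went the same way for 8 of 12 at 1 h, 6 of 8 at 4 h and 14 of 16 at 24 h.

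Each later array was compared with the 0 h array. Since 1 array per time point leaves no estimate of the spread between cultures, no test was run and no p-value is given. A gene was counted where its log2 difference was at least 1 (2-fold) and it was well above background on both arrays. Where it was well above background on one array, the brighter value was set against the higher of the dim array's lowest signal among probes well above background and the dim probe's own value, and is given as "at least". For 35 gene lists fixed before the data were examined, the median log2 difference was set among the medians of 10000 random lists of the same size, each member drawn from the 200 genes closest in mean expression. A list member dim on one array entered at its bound. The rule was checked on simulated data with 200 changed genes. In each of the 3 comparisons it called 50 of 50 genes changed 3-fold, 50 of 50 changed 4-fold, 50 of 50 changed 8-fold and 0 of 50 changed 1.5-fold. It called 1 of 14566 unchanged genes at 1 h, 2 of 14733 at 4 h and 1 of 14758 at 24 h. The noise in these simulations came from the spread between the 1 h and 0 h arrays and lacks the spread between cultures. It also holds no single-array outliers. The changed genes were drawn from genes well above background on all 4 arrays and kept that mark, so none could drop to background. With noise small beside a 3-fold change, the calls at 3-fold and above were nearly fixed in advance. They do not show how the rule does for genes near background.

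Genes named in the text followed a rule fixed before the data were examined. For each time these are the 12 largest increases and 12 largest decreases of at least 2-fold with a gene symbol that is not a clone, antisense or similar name and whose other probes agree in direction, the 3 largest bounds per direction, up to 4 members per list, and 12 genes given whatever their values: IL13RA2, CISH, SOCS1, CCL26, CCL11, CCL2, POSTN, TNC, VCAM1, IL6, ACTA2 and COL1A1. Genes given outside the rule are named as such or are members of a count. Genes of the sex chromosome Y, XIST and genes whose presence varies between people were left out of all tables.

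Alternatives fixed in advance were normexp background correction with an offset of 50, run on the median spot signal because the files have no mean signal, quantile normalization, scaling on the array median, the deposited value table, genes well above background on all arrays, no background filter, the mean over a gene's probes, flagged spots kept, a 1.5-fold and a 3-fold rule, and the 1 h array as baseline. Scaling on 8 spike-in control probes, and measured values for list members dim on one array, were added after the data were seen. Analyses used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9, with R 4.3.3 and limma 3.58.1 for normexp and quantile normalization.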

Results

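Gene expression was measured in normal human lung fibroblasts, a commercial culture of primary connective-tissue cells, before and after addition of interleukin-13 (IL-13), a type 2 cytokine that acts through the IL-4 receptor complex and the transcription factor STAT6. RNA collected at 0 h, and then 1, 4 and 24 h into exposure to 10 ng/ml IL-13, was hybridised to 4 one-colour arrays, 1 array per time point. The question the design poses is which transcripts differed from the 0 h culture at each later time. With 1 array per time point there is no replicate check, no test could be run, and no culture without IL-13 was followed over the same hours in these data. Differences below are described by a fixed rule of size, at least 2-fold with a signal well above background on both arrays, and "higher" and "lower" refer to the arrays compared. The number of arrays limits the precision. Between 49.0% (1 h) and 51.3% (24 h) of the 60901 non-control spots on each array were well above background, which covered 14959 to 15411 named genes per array. Spots of a probe printed 10 times on the same array had a median SD of 0.052 to 0.057 log2 units, which covers spotting and scanning error but not differences between cultures. Of 11296 such spots left after flagged spots were dropped, 0 lay 2-fold or more from the median of their probe. That allows a share of up to 0.0327% (exact 95% interval) among unflagged spots. The interval treats these spots as independent, although they are repeats of the same probes, so it may be too narrow. Spots flagged as population outliers had been removed first, so this share does not cover outlying spots. It also does not carry over to probes that were not printed 10 times. Across genes, the robust SD of the difference between the 1 h and 0 h arrays went from 0.29 log2 units among the dimmest genes to 0.05 among the brightest (deciles of brightness).

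At 1 h, the genes furthest above their 0 h level encoded an eosinophil chemokine and feedback inhibitors of cytokine signalling. CCL26, which encodes eotaxin-3, was 34.5-fold higher, CISH 25.1-fold and SOCS1 5.95-fold higher. CISH and SOCS1 encode inhibitors of JAK-STAT signalling. The transcription factor gene KLF2 was 5.44-fold higher, the kinase gene PIM1 5.14-fold, TMEM26 4.31-fold and the adhesion molecule gene VCAM1 3.87-fold. The other genes among the 12 largest increases were SNORD24 (3.73-fold), SLC25A25 (3.29-fold), MYB (3.27-fold), RASD1 (3.20-fold) and KCNQ5-IT1 (3.10-fold). On the lower side, PRSS16 was 2.79-fold lower, and the interferon-stimulated genes MX2, IFI44L and OAS2 were 2.54-fold, 2.47-fold and 2.43-fold lower. Also among the 12 largest decreases were ARHGEF25 (2.41-fold lower), PI3, which encodes the protease inhibitor elafin (2.37-fold), and the phosphatase gene DUSP2 (2.28-fold). The others were ASPHD2 (2.27-fold), the cytokine gene LIF (2.20-fold), RGS16, a regulator of G-protein signalling (2.15-fold), PPP1R13B-DT and ZNF664-RFLNA (log2 differences of -1.23 and -1.22). In all, 52 of 14766 genes compared were at least 2-fold higher and 22 at least 2-fold lower. Of the 52, 6 were at least 4-fold higher, and 0 genes were 4-fold lower. Arrays simulated without any change gave at most 4 2-fold calls per comparison. Their noise followed the 1 h and 0 h arrays and held no single-array outliers. Across genes, the robust SD of the difference from 0 h was 0.091 log2 units at 1 h, 0.134 at 4 h and 0.198 at 24 h. The simulations may therefore understate how many calls arise without a real change. Under a background correction that adds a fixed offset to every signal (normexp), the counts were 26 higher and 2 lower. CCL26 was then 3.31 log2 units higher in place of 5.11 and TMEM26 2.42-fold higher, and of the 12 largest increases VCAM1, MYB, SNORD24 and KCNQ5-IT1 were under 2-fold. Of the 12 largest decreases LIF alone was still 2-fold lower. With the mean over all probes, ARHGEF25 was 1.69-fold lower.

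Among the gene groups fixed before the data were examined, the STAT6-dependent type 2 response genes stood furthest above the 0 h array at 1 h. Their median log2 difference was 0.17 over 20 measured members, above all 10000 random lists matched on expression. Of the 20, 8 were at least 2-fold higher, among them CCL11, the gene of eotaxin-1 (2.72-fold), CCL2 (2.90-fold) and CCL7 (2.34-fold), and 0 were 2-fold lower. The prostaglandin and lipid mediator genes had a median of 0.07 (99.8th percentile), and 1 of 18 members, the cyclooxygenase-2 gene PTGS2, was 2-fold higher (2.44-fold). PTGS2 was under 2-fold (0.55 log2 units) with normexp. The SOCS family and cytokine feedback genes had a median of -0.01 and a mean of 0.39, since 3 of 20 members were at least 2-fold higher: CISH, SOCS1 and the MAP kinase phosphatase gene DUSP6 (2.22-fold). The immediate early genes moved apart in the same way, with a median of -0.06 (1.36th percentile) and a mean of 0.03. KLF2 and ATF3 (2.73-fold, and 1.97-fold as the mean over its probes) were higher and NR4A2 was 2.07-fold lower. The median lay just above 0 under spike-in scaling. Among NF-kB feedback targets, PTGS2 and TNFAIP6 (2.14-fold) were 2-fold higher, with a list median of -0.04 and a mean of 0.08. Among p53 targets, GADD45A (2.25-fold) and GADD45G (2.33-fold) were higher, against a list median of -0.03 and a mean of 0.03. IL6 was 2.10-fold higher.

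The interferon-stimulated genes were the group furthest below the 0 h array at 1 h. Their median was -0.34 over 32 measured members, below all random lists, and -0.41 when members dim on one array entered with their measured values. Of the 32 members, 29 were below their 0 h level and 6 were at least 2-fold lower, including BST2 (2.05-fold lower) beside MX2, IFI44L and OAS2. TGF-beta response genes had a median of -0.11, also below all random lists, and 23 of 28 members were below 0 h. ID1, an inhibitor of DNA binding, was 2.13-fold lower and KLF10 1.70-fold lower. With normexp, ID1 was 1.89-fold lower, NR4A2 1.71-fold and BST2 1.39-fold lower, and GADD45G 1.84-fold higher, all under 2-fold. With spike-in scaling BST2 (1.95-fold) and NR4A2 (1.97-fold) were also under 2-fold lower. Circadian clock genes had a median of -0.10 (0.27th percentile) with NFIL3 2.01-fold higher, and collagens -0.06 (1.22nd percentile). The collagen median was 0.01 under spike-in scaling and inside the random range with quantile normalization.

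**Figure D1:**
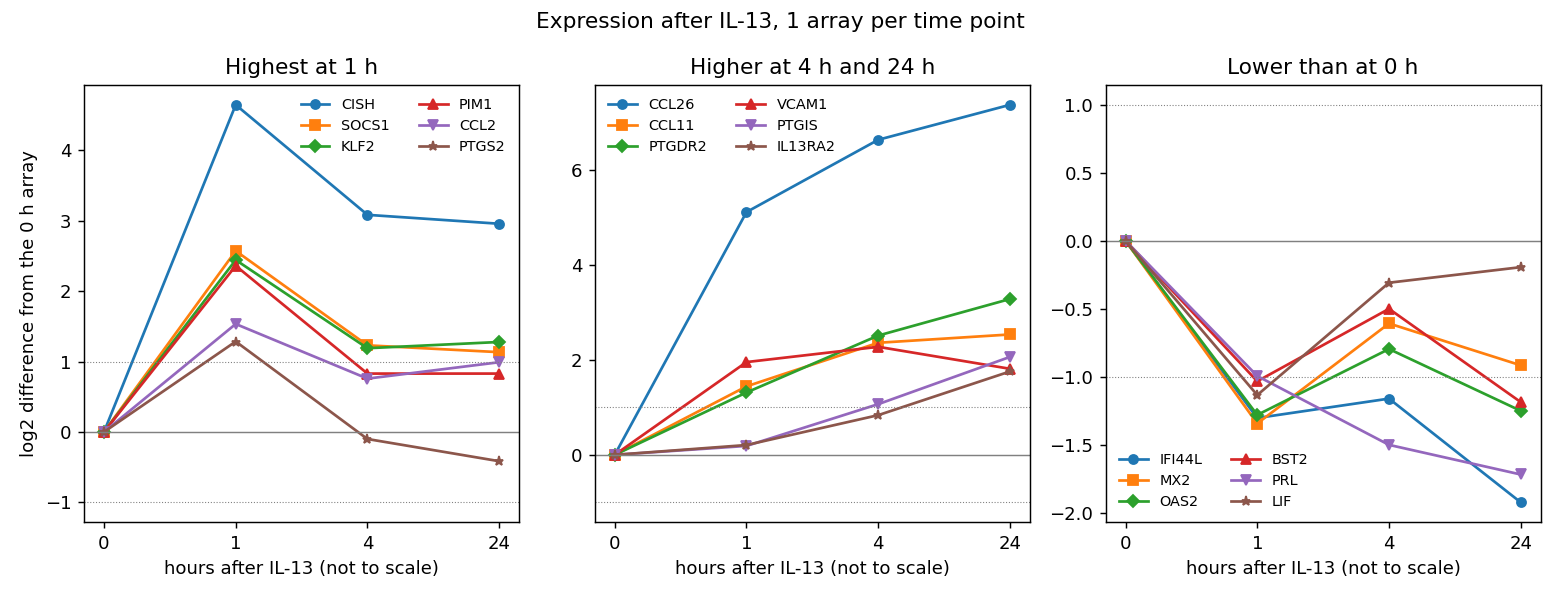
Log2 difference from the 0 h array (vertical axis) against hours of IL-13 exposure (0, 1, 4 and 24 h, horizontal axis, not to scale) for 18 genes, 1 array per time point and so without error bars; dotted lines mark 2-fold. CISH was highest at 1 h (4.65 log2 units) and lower at 24 h (2.96), CCL26 went from 5.11 at 1 h to 7.37 at 24 h, and IFI44L was lowest at 24 h (-1.93).

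At 4 h, CCL26 was 99.1-fold above 0 h and CISH 8.49-fold. PTGDR2, which encodes a prostaglandin D2 receptor, was 5.70-fold higher, CCL11 5.13-fold, VCAM1 4.84-fold and LYPD1 4.11-fold. The ganglioside synthase gene ST8SIA1 was 3.80-fold higher, TMEM26 3.71-fold and CERS1 3.68-fold. They were followed by the cysteinyl leukotriene receptor gene CYSLTR1 (3.49-fold), TSPAN13 (3.36-fold) and the transcription factor gene BATF3 (3.16-fold). CERS1 shares its locus with GDF1 (2.23-fold higher), so the source of that signal is uncertain. SOCS1 (2.35-fold) and KLF2 (2.28-fold) were closer to 0 h than at 1 h. Lower at 4 h were PF4, a platelet chemokine gene (3.67-fold lower), TMEM255B (3.30-fold), the neurotrophic factor receptor gene GFRA3 (3.04-fold), the prolactin gene PRL (2.83-fold), the potassium channel gene KCNT2 (2.32-fold), PI3 (2.31-fold) and IFI44L (2.24-fold). PF4 and TMEM255B were not well above background at 1 h. In all, 47 of 14933 genes compared were at least 2-fold higher, 6 of them at least 4-fold, and 19 were at least 2-fold lower, 0 of them 4-fold. The higher genes made up 71.2% of these calls, and 57.4% (39 higher, 29 lower) when arrays were scaled on spike-in control probes. With normexp the counts were 18 higher and 0 lower. CCL26 was then 28.5-fold higher, PTGDR2 2.22-fold, TMEM26 2.37-fold and TSPAN13 2.12-fold, and VCAM1 and CYSLTR1 were under 2-fold. With the mean over its probes ST8SIA1 was 2.40-fold higher.

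The STAT6-dependent genes had a median of 0.48 at 4 h over 21 measured members, above all random lists, and 6 of the 21 were at least 2-fold higher. Chemokines had a median of 0.16 (99.8th percentile), with CCL26, CCL11 and CCL7 (2.33-fold) 2-fold higher among 13 measured. The chemokine median was inside the random range with normexp (84.7th percentile). Several groups were shifted upwards by small amounts without 2-fold members beyond those already named. NRF2 and oxidative stress genes had a median of 0.12 (above all random lists, 24 of 27 members above 0 h), NF-kB feedback targets 0.12 (99.5th percentile), SOCS family genes 0.10 (98.7th), immediate early genes 0.10 (99.4th) and heat shock genes 0.10 (98.2nd). The immediate early and heat shock medians lay just below 0 under spike-in scaling. Inside the random range were the heat shock median with normexp and with quantile normalization, the SOCS family median with normexp, and the immediate early median with quantile normalization. The interferon-stimulated genes had a median of -0.36, below all random lists, with 27 of 32 members below 0 h and 1, IFI44L, at least 2-fold lower. Cell cycle genes had a median of -0.14, below all random lists, and 31 of 38 members were below 0 h. The largest of these differences were in TTK (1.38-fold lower) and MYBL2 (1.36-fold lower). Growth factors had a median of -0.05 (0.20th percentile) and a mean of 0.03, since ANGPTL4 was at the 2-fold limit (1.85-fold with normexp) and VEGFA 1.69-fold higher. The growth factor median was inside the random range with quantile normalization. Below the range of random lists were also p53 targets (-0.06), matrix metalloproteinases and inhibitors (-0.04), glucocorticoid response genes (-0.02), TGF-beta response genes (-0.02) and non-collagen extracellular matrix genes (0.01). Medians this close to 0 turned sign under at least 1 other scaling, except that of the p53 targets, which stayed between -0.16 and -0.0010. The TGF-beta median was inside the random range with normexp.

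At 24 h, CCL26 was 165-fold and PTGDR2 9.72-fold above 0 h, CISH 7.77-fold and CCL11 5.79-fold. LMBRD2 was 4.64-fold higher, ST8SIA1 4.49-fold, RIMS1, known from synaptic vesicle release, 4.33-fold, the serine protease inhibitor gene SPINT2 4.25-fold, and the prostacyclin synthase gene PTGIS 4.17-fold. GALNT9 (3.98-fold), SMKR1 (3.79-fold) and CYSLTR1 (3.68-fold) completed the 12 largest increases. IL13RA2, which encodes the decoy receptor of IL-13, was 1.15-fold above 0 h at 1 h, 1.78-fold at 4 h and 3.38-fold at 24 h. LMBRD2 was not well above background at 1 h or 4 h. On the lower side, IFI44L was 3.80-fold lower, PRL 3.29-fold, GFRA3 2.75-fold and KCNT2 2.68-fold. They were followed by GLIPR1L2 (2.62-fold), CA5A (2.60-fold), AK9 (2.53-fold), ASPHD2 (2.44-fold), OAS2 (2.38-fold) and the tight junction gene CLDN1 (2.36-fold). ZNF664-RFLNA (log2 difference of -1.23) and the cytokine subunit gene IL23A (2.35-fold) came last of the 12. In all, 67 of 14958 genes compared were at least 2-fold higher, 9 of them at least 4-fold, and 47 were at least 2-fold lower, 0 of them 4-fold. The higher genes were 58.8% of these calls. That share was 70.4% with arrays scaled on the median, 41.4% in the deposited value table and 39.0% with spike-in scaling (53 higher, 83 lower). Spike-in scaling shifted the median of all genes by -0.11 at 24 h and -0.10 at 4 h, whereas the percentiles of list medians are relative to other genes under the same scaling. With normexp the counts were 32 higher and 5 lower. CCL26 was then 46.5-fold higher, PTGDR2 3.33-fold and RIMS1 2.55-fold. CYSLTR1, GALNT9, LMBRD2 and SMKR1 were under 2-fold, and of the 12 largest decreases IFI44L and CLDN1 remained at least 2-fold lower. The mean over all probes of AK9, ASPHD2 and GLIPR1L2 was under 2-fold lower (1.65-fold, 1.58-fold and 1.73-fold), and that of ST8SIA1 was 2.72-fold higher.

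The STAT6-dependent genes had a median of 0.56 at 24 h, above all random lists, with 7 of 22 measured members at least 2-fold higher. It was 0.69 when members dim on one array entered with their measured values. Members of the matrix and contractile lists measured on both arrays differed from 0 h by less than 2-fold at every time. POSTN, the periostin gene, was 1.09-fold, 1.40-fold and 1.66-fold above 0 h at 1, 4 and 24 h, and TNC, the tenascin-C gene, 1.03-fold, 1.20-fold and 1.39-fold. COL1A1 was 0.35 log2 units and ACTA2, the smooth muscle actin gene, 0.55 log2 units above 0 h at 24 h. Collagens had a median of 0.19 (99.5th percentile), with 16 of 20 above 0 h, led by COL6A1 (1.78-fold) and COL5A3 (1.64-fold). Contractile and myofibroblast genes had a median of 0.19 (98.8th percentile), with 20 of 21 above 0 h, among them ACTG2 (1.54-fold), MYL9 (0.59 log2 units) and CNN1 (1.45-fold). The smooth muscle and pericyte markers had a median of 0.27, above all random lists. As listed, they share MYH11, ACTG2, DES, LMOD1, CNN1 and SMTN with the contractile group, so these lists are not independent. Collagen processing and crosslinking genes had a median of 0.17 (99.3rd percentile), with LOXL3 1.42-fold and P4HA1 1.29-fold higher. The contractile median was inside the random range with normexp and quantile normalization, and that of collagen processing with quantile normalization. Non-collagen extracellular matrix genes (0.02) and fibroblast identity genes (0.02, with FGF10 1.64-fold lower) lay below the range of random lists of like expression, and both medians were below 0 under quantile normalization, spike-in scaling and in the deposited value table. The extracellular matrix median was inside the random range with normexp. The fibroblast identity median, at the 2.19th percentile in the main setting, was inside the random range with normexp. It also came inside under median, spike-in and deposited-table scaling. These move every gene by 1 constant per array and can hardly move a list against random lists. The smaller draw of 2000 random lists used for the alternatives may account for that.

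Other groups above the random range at 24 h were the unfolded protein response genes, with a median of 0.24 above all random lists and 23 of 29 members above 0 h (CHAC1 1.53-fold, XBP1 1.44-fold), and cholesterol synthesis and SREBP targets, with a median of 0.20 (99.7th percentile, FASN 1.31-fold). NRF2 and oxidative stress genes had a median of 0.17 (98.9th percentile), inside the range with quantile normalization. Adhesion molecules and integrins had a median of 0.14 (97.9th percentile), inside the range with quantile normalization. It also came inside under median, spike-in and deposited-table scaling, where the smaller draw of 2000 random lists may account for it. Their 2-fold members were VCAM1 (3.51-fold, and 1.55-fold with normexp) and the cadherin gene CDH6 (2.74-fold), while NCAM1 was at least 2.05-fold lower. Leukocyte markers, a list of another cell type, had a median of 0.23 (99.3rd percentile) over 13 measured of 25 on the array, with 10 above 0 h and 0 at 2-fold. FCER1G was 1.34-fold and PTPRC 1.17-fold above 0 h. Interferon-stimulated genes had a median of -0.59, below all random lists, with 28 of 32 below 0 h and 5 at least 2-fold lower, BST2 (2.28-fold) among them. BST2 was 1.30-fold lower with normexp and 1.98-fold as the mean over its probes. ISG20 was the 1 member at least 2-fold higher (2.03-fold), named here after its value was seen, and was under 2-fold with normexp, quantile normalization and spike-in scaling and in the deposited value table. Below the range were also p53 targets (-0.11), matrix metalloproteinases and inhibitors (-0.08) and glucocorticoid response genes (-0.08), although ANGPTL4, a member of the last, was 2.58-fold higher. The metalloproteinase median was inside the range with normexp.

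**Figure D2:**
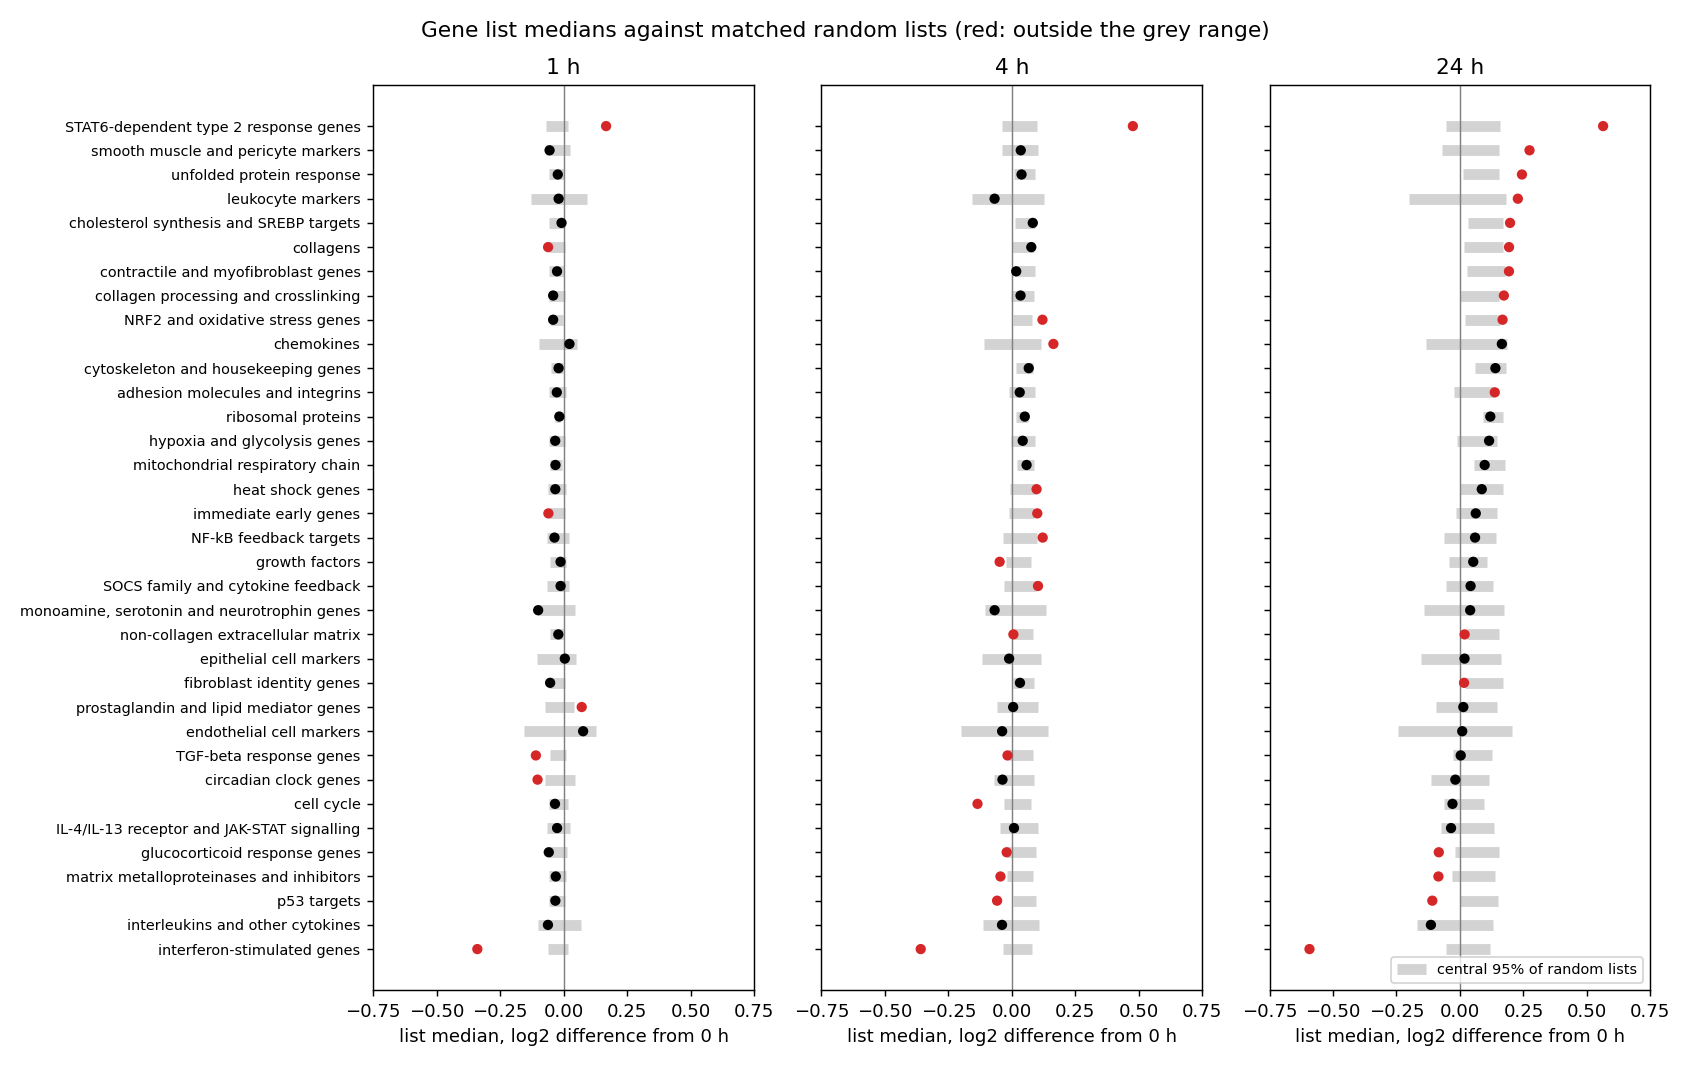
Median log2 difference from the 0 h array (horizontal axis) of 35 gene lists (vertical axis) at 1, 4 and 24 h; grey bars are the central 95% of medians of 10000 random lists matched on size and expression, and red points lie outside them. The STAT6-dependent genes lie furthest to the right at every time (0.17, 0.48 and 0.56) and the interferon-stimulated genes furthest to the left (-0.34, -0.36 and -0.59).

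For 9 of the 35 lists the median lay inside the range of random lists at all 3 times in the main setting. Of these, the monoamine, serotonin and neurotrophin list was below the range with normexp at 1 h and 4 h (percentiles of 1.2 and 1.05). At 24 h the medians were -0.04 for IL-4/IL-13 receptor and JAK-STAT signalling (mean 0.10, IL13RA2 the 1 member at 2-fold), -0.11 for interleukins and other cytokines, 0.11 for hypoxia and glycolysis genes and 0.04 for monoamine, serotonin and neurotrophin genes. They were 0.02 for epithelial markers, 0.01 for endothelial markers, 0.14 for cytoskeleton and housekeeping genes, 0.12 for ribosomal proteins and 0.10 for the mitochondrial respiratory chain. Outside the range were 7 lists at 1 h (2 above, 5 below), 15 at 4 h (7 above, 8 below) and 16 at 24 h (10 above, 6 below), where independent random lists would give 1.75 at each time. Random lists do not share the co-regulation of real ones, so these percentiles describe the 4 arrays and are no test.

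Across the 3 comparisons, 118 genes were at least 2-fold higher and 66 at least 2-fold lower at 1 or more times, and 0 genes were higher at one time and lower at another. The genes 2-fold higher at every time were 13, among them CCL26, CCL11, CCL7, CISH, SOCS1, KLF2, VCAM1 and PTGDR2. With normexp, CCL7 (1.71-fold, 1.71-fold and 1.63-fold) and VCAM1 (1.67-fold, 1.81-fold and 1.55-fold) were under 2-fold at all 3 times and PTGDR2 at 1 h (1.40-fold). Another 38 were 2-fold higher at 1 h and not at 4 h or 24 h, including PIM1, PTGS2, ATF3, DUSP6 and CCL2, which was 1.69-fold above 0 h at 4 h and 1.99-fold at 24 h. IL6 was 2-fold higher at 1 h and 24 h (2.05-fold) but 1.55-fold at 4 h, and under 2-fold at 24 h with every other scaling but that on the median. A further 21 were 2-fold higher at 4 h and 24 h but not at 1 h, including PTGIS, CYSLTR1, ST8SIA1, RIMS1 and SPINT2. Of these, CYSLTR1 was under 2-fold at both times with normexp (1.49-fold and 1.59-fold), and PTGIS and RIMS1 were under 2-fold at 4 h with normexp (1.89-fold and 1.44-fold) and with spike-in scaling (1.95-fold and 1.99-fold). Lower at every time were 4 genes, AK9, IFI44L, PPP1R13B-DT and LOC101928273, and with normexp 0 genes, since none was 2-fold lower at 4 h. AK9 was under 2-fold at all 3 times with the mean of its probes as well. All comparisons use the same 0 h array. Among genes measured in both comparisons, the 4 h and 24 h arrays shared 34 higher genes, where independent lists would share 0.20 and simulated unchanged arrays shared at most 1, and 7 lower genes, where independent lists would share 0.05 and simulated arrays shared 0. The 1 h and 24 h arrays shared 14 higher and 13 lower genes, and the 1 h and 4 h arrays 13 and 6. Part of this overlap may come from the shared array. The simulated arrays took their noise from the 1 h and 0 h arrays and held no single-array outliers. They may therefore understate the overlap that arises without a real change. Directly between later arrays, 44 genes were at least 2-fold higher and 49 lower at 24 h than at 1 h, 17 higher and 30 lower at 4 h than at 1 h, and 19 higher and 18 lower at 24 h than at 4 h.

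Genes well above background on one of the arrays compared give a bound. Bounds of at least 2-fold were found for 68 genes higher and 49 lower at 1 h, 54 and 72 at 4 h, and 52 and 89 at 24 h. The largest were POU2F3 at 1 h (at least 7.83-fold higher), OR56A5 at 4 h (at least 5.46-fold higher) and LYPD8 at 24 h (at least 6.16-fold higher). The largest in the other direction was DAO, at least 6.26-fold lower at 1 h, 7.85-fold at 4 h and 8.29-fold at 24 h. Each of these genes was well above background on a single array. Genes well above background on one array alone and 2-fold brighter there than on each other array numbered 38 at 0 h, 53 at 1 h, 17 at 4 h and 24 at 24 h.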

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

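Probes without a matched gene name carried differences of at least 2-fold that no comparison above uses. At 1 h, 51 such probes were higher and 19 lower than at 0 h among 6817 compared. At 4 h, 26 were higher and 41 lower among 7124, and at 24 h 33 were higher and 67 lower among 7182. Many of these probes are annotated as long non-coding transcripts, and their genes were not resolved. They are reported as values without an explanation.

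The tests of the 0 h array and of scaling for the interferon-stimulated genes were chosen after the medians were seen. The tests of time in culture and of single-spot signals were set before.

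The interferon-stimulated genes were below the 0 h array at every later time, by a median of -0.34 log2 units at 1 h, -0.36 at 4 h and -0.59 at 24 h. Median, spike-in and deposited-table scaling move every gene by 1 constant per array, so they could hardly change the list's place among random lists. Quantile normalization and normexp could have changed it, and with both the median at 24 h stayed below all random lists. Over the other scalings and normexp it came no closer to 0 than -0.32. Scaling between arrays is thus argued against by quantile normalization and normexp alone. A high 0 h array alone cannot be told apart from a response for the part already present at 1 h (-0.3399), because no second 0 h array is among these data. The difference between 4 h and 24 h holds no 0 h value, so a high 0 h array could not cause that difference. It says nothing about the part present at 1 h. The 24 h array lay below the 4 h array by a list median of -0.1834, below all random lists (range -0.071 to 0.060), with 27 of 29 members lower, and by -0.13 to -0.22 under the other scalings and normexp, again below all random lists. Whether the list fell further between 1 h and 24 h stays open. The median of 24 h against 1 h was -0.0656 (0.7th percentile, random range -0.041 to 0.126), with 17 of 28 members below 0. It came to 0.0018 with median scaling and -0.24 with spike-in scaling. The 4 h array lay above the 1 h array by 0.15, so the 3 later arrays did not fall in steady order, and single arrays give no measure of the spread between cultures, which may account for the difference between 4 h and 24 h as well. The reading of these comparisons was revised more than once after their values were seen. The percentile of 24 h against 1 h was first taken as enough, then a median larger in size than that of 4 h against 1 h was also asked for, and the 24 h against 4 h comparison was added as a test last. It meets that size rule in the main setting but not with median scaling (-0.18 against 0.21). Time in culture, medium handling included, also stays open, since 0 of the arrays came from an untreated culture at a later time, so a lowering by IL-13 remains an untested hypothesis.

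Some genes were well above background on the 0 h array alone and at least 2-fold brighter there than on each later array, such as DAO, GPR52 and HASPIN. They numbered 38. The same count was 53 on the 1 h array, 17 on the 4 h array and 24 on the 24 h array. The prediction for single-spot artefacts asked for a 0 h count within the exact 95% Poisson interval around the highest of the others. The 0 h count lies under its upper limit of 69.3 but also below its lower limit, so the prediction as worded was not met. The 1 h array alone set that interval, and the 4 h and 24 h arrays had fewer such genes than the 0 h array. This check therefore cannot decide, and single-spot artefacts of one array stay open as an explanation. No biological explanation was tested for them.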

How the results depend on the processing

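The spike-in scaling and the measured values for dim list members were chosen after the data were seen, and the other settings before. Leaving out the background filter moved the counts most, to 545 higher and 438 lower at 1 h, against 171 and 94 with the 1.5-fold rule. Signal over background thus limits what these arrays show. Of the 82 counts under other settings, 46 stayed within 1.5 times the reported count. For named genes 3680 values stayed within their noise, 984 moved and 22 with a 2-fold difference changed sign. For list medians 736 stayed, 380 moved and 4, all of lists outside the random range, changed side of the random median. These 22 and 4 changes all came with the 1 h array as baseline, which asks another question (change after 1 h). Lists inside the random range are not among the 4, and some changed side under other scalings. Examples were growth factors at 24 h (66.7th percentile, and 33.0th at the lowest) and interleukins at 1 h (12.8th, and 63.1st at the highest). CCL26, CCL11, CISH, SOCS1 and IFI44L at 24 h kept their direction and at least 2-fold under normexp, quantile, median and spike-in scaling and in the deposited value table. Median, spike-in and deposited-table scaling move every gene by 1 constant per array, and list medians with them. For quantile normalization and normexp the cause of differences in list medians was not tested.

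Normexp gave 26 genes higher and 2 lower at 1 h, 18 and 0 at 4 h, 32 and 5 at 24 h, and 15 shared by 4 h and 24 h against 41. The offset added to every signal pulls the folds of dim genes towards 1 by construction. Without a background filter the counts were 545 and 438, 557 and 589, and 624 and 634, with 568 shared, because genes at background level enter. The 1.5-fold rule gave 171 and 94, 187 and 163, and 276 and 320, with 183 shared, and the 3-fold rule 14 and 1, 13 and 5, and 22 and 3, with 11 shared, as a lower or higher threshold does. The mean over a gene's probes gave 34 lower at 4 h against 19 (the cause was not tested). The deposited value table gave 78 lower at 24 h against 47, and spike-in scaling 29 lower at 4 h and 83 at 24 h. In both, a different constant per array moves every gene alike, by -0.09 and -0.11 at 24 h.

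With the 1 h array as baseline, 17 genes were higher and 30 lower at 4 h and 44 higher at 24 h, with 23 shared. Genes further from 0 h at 1 h than later then changed sign. At 4 h and 24 h the log2 differences from 1 h were -1.56 and -1.69 for CISH, -1.34 and -1.44 for SOCS1, -1.25 and -1.17 for KLF2, -0.22 and -1.05 for TMEM26, -0.49 and -0.17 for KCNQ5-IT1, -0.0037 and -0.0925 for CCL7, and 0.0938 and 0.19 for PPP1R13B-DT. At 4 h they were 0.0449 for AK9, 0.14 for IFI44L and 0.0368 for PI3. At 24 h they were 0.15 for DUSP2, -0.0333 for IL6, 0.0300 for OAS2, 0.46 for PRSS16 and -0.14 for VCAM1. List medians on this baseline were 0.0472 for the SOCS family, 0.15 for interferon-stimulated genes and 0.13 for TGF-beta response genes at 4 h, and 0.0029 for STAT6-dependent genes at 24 h. No paired analysis was possible because each time point has 1 array.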

Other observations

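The genes of this and the next paragraph were named after their values were seen. Of the 5 LRRC8 genes, whose products form volume-regulated anion channels, LRRC8B, LRRC8C and LRRC8D were 2.61-fold, 2.92-fold and 2.77-fold higher at 4 h and 2.52-fold, 3.10-fold and 2.49-fold at 24 h. LRRC8A (1.05-fold and 1.04-fold) and LRRC8E (0.997-fold and 0.999-fold) lay between 0.926-fold and 1.09-fold of the 0 h level under the other scalings at these times, with a direction that depended on the scaling. With normexp, LRRC8B (0.66 and 0.69 log2 units) was under 2-fold at both times and LRRC8C (0.89) at 4 h. GLI1, a transcription factor of hedgehog signalling, was 3.12-fold and 3.47-fold higher, and the desmosome gene DSP 2.28-fold and 2.64-fold (under 2-fold at 4 h with normexp). The water channel gene AQP1 was 1.84-fold and 2.31-fold higher and the imprinted gene MEST 1.68-fold and 3.03-fold.

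Several regulators were 2-fold higher at 1 h and closer to 0 h later. CH25H, which encodes cholesterol 25-hydroxylase, was 3.10-fold higher at 1 h and 1.15-fold at 4 h. RGS1 was 3.10-fold and 1.21-fold higher at those times (under 2-fold at 1 h with normexp), the kinase genes MAP3K14 2.84-fold and 1.30-fold and MAP3K8 2.58-fold and 1.44-fold, and the transcription factor genes PRDM1 2.82-fold and 1.20-fold and GATA6 2.73-fold and 1.70-fold.

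The tests in the next paragraph were set before their results were seen.

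Genes at least 2-fold higher at 24 h lay next to one another more often than random draws. Among 67 such genes there were 5 neighbouring pairs (LRRC8B with LRRC8C, CCL7 with CCL11, PTGDR2 with ZP1, KCNJ12 with KCNJ18, VEPH1 with PTX3), where 10000 draws gave a mean of 0.29 and at most 4, so chance order of genes is argued against for these calls. The same 5 pairs were found with quantile normalization, spike-in scaling and the deposited value table, and 7 pairs with median scaling. In each of these 0% of draws gave as many. With normexp, LRRC8B, CCL7, ZP1 and KCNJ12 were under 2-fold, and among 32 genes 1 pair was left (VEPH1 with PTX3), as in 6.57% of draws, so the excess rests on the treatment of background. Related or overlapping genes read by one another's probes stay open as an explanation, since dropping pairs with a shared symbol stem or overlapping spans left 1 pair, PTGDR2 with ZP1. The bound set in advance, the 95th percentile of draws, was itself 1 and too coarse, since 21.1% of draws gave as many. KCNJ12 and KCNJ18 are near-identical in sequence, so 1 transcript may be counted there as a pair, and joint regulation of neighbours remains an untested hypothesis.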
